A study of Mus musculus with 12 samples.

How the data were processed

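Gene expression was measured by RNA-seq in 12 libraries of sorted mouse cells. The groups were 4 libraries of P80R B-ALL cells from recipients 1300, 1301, 1302 and 1308, 4 of Pax5-deficient fetal liver progenitors (Pax5 KO) and 4 of fetal liver pro-B and pre-BI cells with intact Pax5 (Pax5 WT), per the labels. Per the labels' protocols, sorted cells were lysed, RNA was isolated with a column kit for small samples and libraries were made with the SMART-Seq v4 full-length kit, which does not mark strand. Per the submitters' processing notes, fastp, STAR 2.7.8a and featureCounts were used with the mm39 build. The annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here.

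The deposited signal values are scaled read counts: every value (100% of them, within a tolerance of 0.001) was a whole multiple of the smallest positive value of its library, so the authors had divided whole counts by 1 factor per library, between 0.723 and 1.38. How these factors were estimated is not given in the sources used here. Multiplying by the factor gave back whole reads, 24914250 to 43513852 per library, which were used for depths, shares of reads and counting intervals. The table held 21885 genes, of which 5237 were at 0 in every library, and 21780 identifiers matched a symbol in a mouse annotation of an older build, GENCODE M21, while 105 did not. That annotation was used for names and exon lengths only, and no coordinates are given. The 13 mitochondrially encoded genes were listed at 0 in all libraries, so this list was not tested, and their share could not serve as a sign of RNA quality.

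Values were analysed as log2 of the value plus 1. Genes with a value of at least 10 in at least 4 libraries were tested, 12200 in all. The test was limma 3.58.1 in R 4.3.3 (a linear model per gene with moderated variances, trend and robust options, two-sided), fitted to all 12 libraries with a mean per group, so that the 3 comparisons shared the estimate of the spread. Adjusted p values are Benjamini-Hochberg within each comparison, with a threshold of 0.05. The plan written before the data were examined had named edgeR's quasi-likelihood test on counts. Because the deposited values were scaled, limma was used instead, camera was run on the log2 values in place of log2 CPM, and genes for the position measure were chosen with limma. The edgeR test (edgeR 4.0.16) on recovered reads became an alternative. The planned share of the leading immunoglobulin V segment was not analysed here.

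The 25 gene lists were fixed before the data were examined, and 24 had at least 3 tested members. They cover Pax5-activated and Pax5-repressed genes, early B-lineage, later B-cell, stem and multipotent progenitor and fetal-program genes, HIF pathway regulators, hypoxia-response, oxidative phosphorylation, S-phase, G2/M, interferon-response, IL-7 receptor with JAK and STAT5, RAS and MAPK feedback, p53 target, immediate-early and heat-shock, cytosolic ribosomal protein and mitochondrially encoded genes, and markers of T-lineage, NK and innate lymphoid, plasmacytoid dendritic, granulocyte and monocyte, macrophage, erythroid and hepatocyte cells. Lists of endothelial and stromal markers were added after the data were seen. Each list was tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison, and again with the correlation estimated per list. That estimate used all 12 libraries, so the spread between B-ALL libraries entered it for Pax5 KO and Pax5 WT too.

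Genes named in the text followed a rule fixed before the data were examined. Pax5, Epas1, Hif1a, Ebf1 and Flt3 were always named, and results for some other genes eligible under this rule are not reported here. In each comparison up to 8 genes per direction with the largest log2 difference were eligible among those past the threshold, with every library of a group above every library of the other and a CPM of at least 10 in the higher group, and up to 3 members of each list with the smallest adjusted p. The text takes them from the top of each ranking, at most 4 per direction and 2 per list. Genes chosen after their values were seen are named as such. For a gene at 0 in a whole group, the fold of the means is a lower bound from a floor of 3 reads per library. In list medians such a gene was set to the mean log2 value of the other group less that of the floor, and to 0 where this passed 0. For 1 to 3 reads in a group, the ratio is given with a 95% counting interval. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

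The position of each B-ALL library was the slope of its difference from the Pax5 WT mean on the difference between the Pax5 KO and Pax5 WT means, over genes chosen on 2 libraries of each group and measured on the other 2, averaged over the 36 divisions. The overlap of the B-ALL comparisons was set beside unchanged simulated groups, independent lists and a division of the B-ALL libraries into 2 and 2. KO and WT libraries carry the same numbers 1 to 4, but the labels do not say that a number marks a shared litter or day, and the fit had no block.

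The gene and list tests were tried on simulated counts. These had 1 mean per gene common to all groups, the factor of each library, and a spread per group set by the gene's level. For the gene test 200 genes were changed, 50 at each fold. For P80R B-ALL and Pax5 KO, 26%, 72%, 82% and 92% of genes changed 1.5, 2, 4 and 8-fold were recovered among 12531 tested. For P80R B-ALL and Pax5 WT the shares were 34%, 72%, 84% and 94% among 12513, and for Pax5 KO and Pax5 WT 20%, 70%, 84% and 98% among 12490. The shared spread was too small for the variable B-ALL group and too large for the others: 87 of 223 calls (39.0%) were false for P80R B-ALL and Pax5 KO, 77 of 219 (35.2%) for P80R B-ALL and Pax5 WT, and 0 of 136 for Pax5 KO and Pax5 WT. With the 8 libraries of each pair alone the false share was 3.39%, 1.61% and 3.91%, at 114, 122 and 172 recovered genes. The fit to all 12 libraries was kept, and the counts from each pair alone are printed beside it. In the simulated lists, 3 of 3 changed lists were found and 0 of 21 others in each comparison. Genes were drawn independently there, so this check does not cover correlation between the genes of a list. For the position, B-ALL values were set at 0.5 between the real Pax5 WT and Pax5 KO means with added noise. This was recovered as 0.502, with no genes moved off that line. The tests of marker ranks, Epas1 ratios and gene length were not simulated.

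Alternatives were RLE, upper-quartile and TMM scaling, pseudocounts of 0.5 and 5, no filter and a CPM of at least 5, limma voom with a weight per group, fits without the robust option, fits of each pair alone, a replicate block, DESeq2 1.42.0 and edgeR on recovered reads, thinning to the smallest library, leaving out each library in turn, and leaving out recipients 1300 and 1308 together. For the lists, fry and the estimated correlation were also used. Camera tests a list against the other genes, while fry, a rotation test, tests it against no change. Ranges of a list's adjusted p over all alternatives include fry, which is named where it gave the lowest value. Plots were drawn with matplotlib 3.10.9.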

Results

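The data are gene-level RNA-seq values of 12 mouse libraries made with a full-length SMART-Seq v4 kit from sorted cells, in 3 groups of 4. The P80R B-ALL group held GFP-positive leukaemia cells of 4 primary recipients, numbered 1300, 1301, 1302 and 1308, in which the PAX5 P80R mutant had given rise to B-cell acute lymphoblastic leukaemia. The Pax5 KO group held early lymphoid progenitors at the common lymphoid progenitor and pre-pro-B stage from Pax5-deficient fetal liver. The Pax5 WT group held pro-B and pre-BI cells from fetal liver with intact Pax5. Depth was 36871775 to 43513852 reads per library in Pax5 KO, 33191950 to 39465256 in Pax5 WT and 24914250 to 29386256 in P80R B-ALL. Rank correlations between libraries of a group were 0.996 to 0.997 in Pax5 KO, 0.991 to 0.997 in Pax5 WT and 0.899 to 0.954 in P80R B-ALL, and the median standard deviation of a gene's log2 value was 0.11, 0.16 and 0.47 in the same order. Values are scaled read counts, given as mean ± SD with n = 4 libraries per group. Differences are on the log2 scale after adding 1 and are given with their standard error (SE) and the adjusted p of limma. Gene lists are described by how many tested members passed an adjusted p of 0.05 over all genes. These counts come from the fit to all 12 libraries. For P80R B-ALL against Pax5 KO and Pax5 WT, 39.0% and 35.2% of its calls were false in simulated data. Counts adjusted over the list alone are given where they were different, and medians with members at 0 in a group set to their bound likewise. The list test was run with a preset correlation between genes, and every passing list is also given its adjusted p with an estimated correlation. The estimate drew on all 12 libraries in every comparison, so the spread between B-ALL libraries also entered it for Pax5 KO and Pax5 WT. Where leaving out 1 library, or recipients 1300 and 1308 together, changed whether a list passed, the adjusted p without them follows. Where such an omission moved the median of a list by over 1.5 times or turned its sign, the median without those libraries is given for a passing list, and the lowest and highest median over leaving out 1 library for the others. Where leaving out 1 library moved a mean of at least 10 by over 1.5 times, the mean without it is given in parentheses. Genotype was confounded with the sorted stage in every comparison. No batch labels were given.

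The knockout was checked first. Pax5, the transcription factor of B-lineage commitment (ENSMUSG00000014030), was at 229.9, 247, 267 and 266 in the 4 Pax5 KO libraries and between 6194 and 7315 in the Pax5 WT libraries, so that all 8 labels matched the gene's level. Gene-level counts do not show whether the remaining reads fell in the deleted part of the gene. The B-ALL libraries of recipients 1300, 1301, 1302 and 1308 had 847, 1146, 1316 and 255, and the reads were not separated into mutant and endogenous Pax5.

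**Figure D1:**
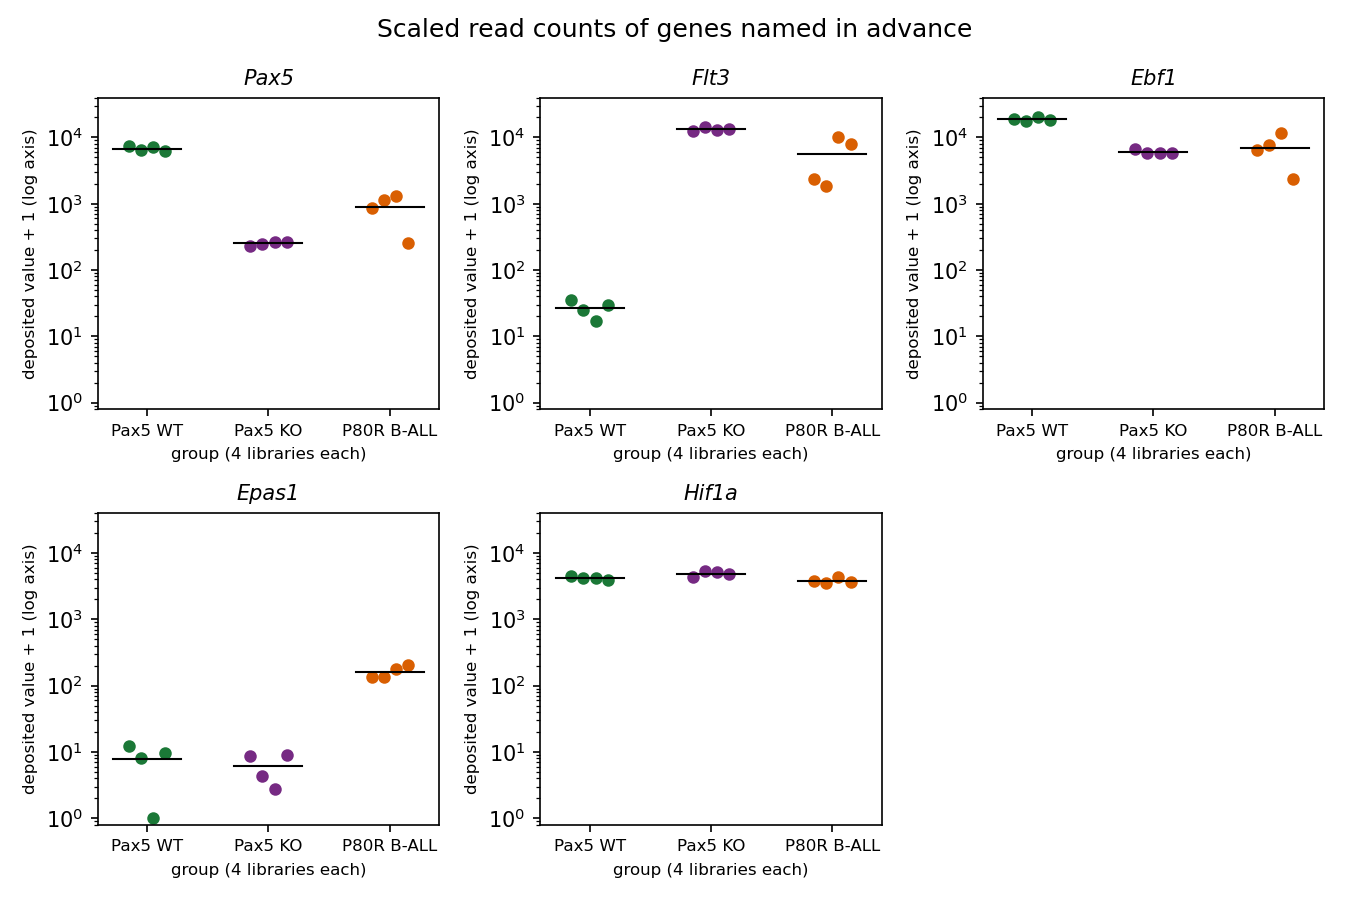
Scaled read counts plus 1 (log axis) of Pax5, Flt3, Ebf1, Epas1 and Hif1a in each group, 1 point per library, with a line at the mean of the 4 libraries. Epas1 was between 132 and 205 in the 4 P80R B-ALL libraries and at most 11.3 in the other 8.

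The comparison of Pax5 KO with Pax5 WT gives the difference between the 2 fetal liver populations used as references for the leukaemia. Pax5-activated genes were far lower in Pax5 KO, and stem and multipotent progenitor genes were higher. Flt3, a cytokine receptor of early progenitors (ENSMUSG00000042817), was at 13184 ± 815 in Pax5 KO and 25.6 ± 7.68 in Pax5 WT (log2 difference 9.00 ± 0.47 SE, adjusted p = 7.77e-08). Ebf1, a B-lineage transcription factor (ENSMUSG00000057098), was lower but well expressed, at 5987 ± 438 against 18818 ± 980.4 (log2 difference -1.65 ± 0.35 SE, adjusted p = 0.00317).

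Among Pax5-activated genes, 17 of 19 tested members were lower and 2 not past the threshold (median -4.43 log2, adjusted p = 6.34e-14, adjusted p = 0.00576 with an estimated correlation). Cd79a, a signalling chain of the B-cell receptor, was at 2485 ± 116 against 45783 ± 3517, and the adaptor gene Blnk at 116 ± 17.2 against 15702 ± 839. Among Pax5-repressed genes, 12 of 15 tested members were higher and 3 not past the threshold (12 higher and 1 lower adjusted over the list alone, median 3.95 log2, adjusted p = 1.96e-07, adjusted p = 0.0405 with an estimated correlation). Emb was at 16212 ± 855 against 1253 ± 108. Early B-lineage genes fell on balance. Of this list, 2 of 19 tested members were higher and 9 lower (median -0.99 log2, adjusted p = 7.01e-05, adjusted p = 0.0607 with an estimated correlation). In this list Vpreb3 was at 24.7 ± 12.7 against 20562 ± 2631 and Pou2af1 at 1023 ± 101 against 29867 ± 1106. Of the later B-cell genes, 5 of 15 tested members were lower and 10 not past the threshold (0 higher and 7 lower adjusted over the list alone, median -2.12 log2, adjusted p = 0.00341, adjusted p = 0.262 with an estimated correlation), among them Cd22 (log2 difference -2.81) and Ms4a1, which encodes CD20 (log2 difference -9.68).

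Stem and multipotent progenitor genes were higher in Pax5 KO, where 8 of 13 tested members were higher and 5 not past the threshold (median 1.20 log2, adjusted p = 0.00146, adjusted p = 0.0495 with an estimated correlation). Cd34 was at 2706 ± 207 against 5.97 ± 3.28. Fetal-program genes included Hmga2, at 3695 ± 281 against 14.7 ± 4.18, and Igf2, at 39.6 ± 9.69 against 1.56 ± 1.88. Here 6 of 10 tested members were higher and 4 not past the threshold (7 higher and 1 lower adjusted over the list alone, median 1.94 log2, 1.65 with members at 0 in a group set to their bound, adjusted p = 0.00442, adjusted p = 0.0607 with an estimated correlation). Immediate-early and heat-shock genes rose, with Egr1 at 26411 ± 956 against 1004 ± 179.8. Here 11 of 19 tested members were higher and 1 lower (median 1.61 log2, adjusted p = 0.00013, adjusted p = 0.0964 with an estimated correlation). Interferon-response genes were mostly higher. Of this list, 17 of 27 tested members were higher and 3 lower (20 higher and 3 lower adjusted over the list alone, median 2.34 log2, adjusted p = 3.16e-05, adjusted p = 0.262 with an estimated correlation), with Irf9 (log2 difference 2.02) and Rtp4 (log2 difference 3.88) having the smallest p.

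All cell-cycle genes that passed the threshold were lower in Pax5 KO. Of the G2/M genes, 25 of 28 tested members were lower and 3 not past the threshold (median -0.82 log2, adjusted p = 8.16e-13, adjusted p = 0.0854 with an estimated correlation). Ube2c was at 8455 ± 151 against 18973 ± 1740. Of the S-phase genes, 12 of 26 tested members were lower and 14 not past the threshold (median -0.39 log2, adjusted p = 5.91e-06, adjusted p = 0.253 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was at 13411 ± 411 against 36841 ± 1314. Of the cytosolic ribosomal protein genes, 21 of 48 tested members were lower and 27 not past the threshold (0 higher and 32 lower adjusted over the list alone, median -0.39 log2, adjusted p = 5.60e-09, adjusted p = 0.335 with an estimated correlation). Oxidative phosphorylation genes had 1 of 31 tested members lower and 30 not past the threshold (median -0.19 log2, adjusted p = 0.0204, adjusted p = 0.593 with an estimated correlation, median -0.12 without library 4 of Pax5 WT, adjusted p = 0.104 without library 4 of Pax5 WT, and 0.00577 to 0.593 over all alternatives), the lower member being Cox5a.

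Markers of several other blood lineages were higher in Pax5 KO than in Pax5 WT, while erythroid markers did not pass. Mpo, the myeloperoxidase of myeloid cells, was at 4880 ± 192 against 1.25 ± 1.89, and Siglech, a plasmacytoid dendritic cell receptor, was at 1195 ± 24.7 in Pax5 KO and 0 in Pax5 WT, at least 419.9-fold higher. Granulocyte and monocyte markers had 13 of 16 tested members higher and 3 not past the threshold (15 higher and 0 lower adjusted over the list alone, median 6.04 log2, 4.45 with members at 0 in a group set to their bound, adjusted p = 3.75e-06, adjusted p = 0.229 with an estimated correlation). Plasmacytoid dendritic cell markers had 8 of 11 tested members higher and 3 not past the threshold (10 higher and 0 lower adjusted over the list alone, median 4.61 log2, adjusted p = 0.000795, adjusted p = 0.325 with an estimated correlation). NK and innate lymphoid markers had 8 of 10 tested members higher and 2 not past the threshold (median 4.06 log2, 3.09 with members at 0 in a group set to their bound, adjusted p = 3.21e-05, adjusted p = 0.104 with an estimated correlation). T-lineage markers had 7 of 13 tested members higher and 6 not past the threshold (median 1.53 log2, adjusted p = 0.000776, adjusted p = 0.127 with an estimated correlation). Macrophage markers had 4 of 11 tested members higher and 7 not past the threshold (median 0.87 log2, 0.00 with members at 0 in a group set to their bound, adjusted p = 0.0274, adjusted p = 0.447 with an estimated correlation). Erythroid markers had none of 12 tested members past the threshold (median 0.37 log2, 0.00 with members at 0 in a group set to their bound, adjusted p = 0.716, median from 0.22 without library 3 of Pax5 KO to 0.48 without library 2 of Pax5 KO), with 1 higher and 0 lower at an unadjusted p under 0.05 in limma and adjusted p = 0.629 in the rotation test fry. Only 3 hepatocyte markers were tested, with 2 of 3 tested members higher and 1 not past the threshold (median 5.49 log2, adjusted p = 0.0349, adjusted p = 0.127 with an estimated correlation, adjusted p = 0.0803 without recipients 1300 and 1308, 0.0521 without recipient 1300, 0.0541 without recipient 1302 and 0.0512 without recipient 1308, and from 5.83e-07 with fry to 0.127 over all alternatives). Of the 2 lists added after the data were seen, endothelial markers had 4 of 7 tested members higher and 3 not past the threshold (median 3.03 log2, adjusted p = 0.00908, adjusted p = 0.212 with an estimated correlation). Stromal markers had 4 of 9 tested members higher and 5 not past the threshold (median 2.29 log2, adjusted p = 0.00908, adjusted p = 0.212 with an estimated correlation, median 1.41 without library 1 of Pax5 KO). Enpep, the BP-1 antigen of pro-B and pre-B cells, and Alpl were the genes with the largest falls, at 2.28 ± 4.57 against 19069 ± 573 and 0.792 ± 0.915 against 8356 ± 501.

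Epas1, which encodes HIF-2α (ENSMUSG00000024140), was near 0 in both fetal liver groups, at 5.14 ± 3.12 and 6.74 ± 4.83 (log2 difference -0.02 ± 0.74 SE, adjusted p = 0.99). Hif1a (ENSMUSG00000021109) was at 4886 ± 394 and 4230 ± 209.8 (adjusted p = 0.134). HIF pathway regulators had 4 of 10 tested members higher and 6 not past the threshold (median 0.35 log2, adjusted p = 0.0614, adjusted p = 0.0445 without recipients 1300 and 1308 and 0.0397 without recipient 1300, and from 0.000541 with fry to 0.192 over all alternatives), among them Egln3, a HIF prolyl hydroxylase, at 1588 ± 63.3 against 64.9 ± 21.8. Hypoxia-response genes went both ways, with 5 of 33 tested members higher and 11 lower (6 higher and 12 lower adjusted over the list alone, median -0.38 log2, adjusted p = 0.0274, adjusted p = 0.0891 with an estimated correlation), Bnip3 falling (log2 difference -2.05) and the glucose transporter gene Slc2a3 rising (log2 difference 1.36). Genes of the IL-7 receptor, JAK and STAT5 pathway had 8 of 22 tested members higher and 2 lower (median 0.44 log2, adjusted p = 0.0604, adjusted p = 0.0445 without recipients 1300 and 1308, 0.0357 without recipient 1300, 0.0336 without recipient 1301 and 0.0459 without recipient 1302, and from 0.00437 with fry to 0.336 over all alternatives). RAS and MAPK feedback genes had 4 of 19 tested members higher and 1 lower (median 0.86 log2, adjusted p = 0.104, adjusted p = 0.0205 without recipient 1301, and 0.0205 to 0.634 over all alternatives), with Ier3 (log2 difference 4.93) and Spry4 (log2 difference 5.97) higher. The p53 target genes had 5 of 17 tested members higher and 3 lower (median 0.21 log2, adjusted p = 0.826). Over all 12200 genes tested, limma called 4193, of which 2449 were higher and 1744 lower in Pax5 KO. The 8 libraries of this pair alone gave 7901, and in simulated data 0 of 136 calls of the fit to all libraries were false, against 3.91% with the pair alone.

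The comparison of P80R B-ALL with Pax5 WT asks how the leukaemia differed from normal fetal pro-B and pre-BI cells. The leukaemia had lower Pax5, high Flt3, and Epas1 in every recipient. Pax5 was at 891 ± 466 against 6734 ± 542 (log2 difference -3.15 ± 0.39 SE, adjusted p = 3.85e-05). Epas1 was at 162 ± 35.3 against 6.74 ± 4.83 (log2 difference 4.85 ± 0.74 SE, adjusted p = 0.000189), and every B-ALL library was above every Pax5 WT library. This level was low, with 102, 107, 142 and 148 reads in recipients 1300, 1301, 1302 and 1308. Epas1 therefore missed the filter of the alternative with a CPM of at least 5 and was not tested there. Flt3 was at 5559 ± 4078 against 25.6 ± 7.68 (log2 difference 7.40 ± 0.47 SE, adjusted p = 2.40e-07), and Ebf1 at 6999 ± 3812 against 18818 ± 980.4 (log2 difference -1.64 ± 0.35 SE, adjusted p = 0.00213).

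Among Pax5-activated genes, 14 of 19 tested members were lower and 5 not past the threshold (1 higher and 15 lower adjusted over the list alone, median -3.23 log2, adjusted p = 7.33e-06, adjusted p = 0.0812 with an estimated correlation). Cplx2 was at 60.5 ± 54.6 (38.5 without recipient 1302) against 5691 ± 247 and Plekha2 at 5038 ± 886 against 12154 ± 934. Among Pax5-repressed genes, 12 of 15 tested members were higher and 3 not past the threshold (13 higher and 0 lower adjusted over the list alone, median 2.76 log2, adjusted p = 2.27e-06, adjusted p = 0.0812 with an estimated correlation). Grap2 was at 711 ± 139 against 103 ± 5.28. Early B-lineage genes had 2 of 19 tested members higher and 10 lower (median -0.60 log2, adjusted p = 0.0168, adjusted p = 0.214 with an estimated correlation, median -0.36 without recipients 1300 and 1308, median -0.93 without recipient 1301, adjusted p = 0.171 without recipients 1300 and 1308, and from 6.53e-05 with fry to 0.214 over all alternatives). In that list Tcf3, which encodes the E2A proteins, fell (log2 difference -2.57) and Il7r, the interleukin-7 receptor, rose (log2 difference 1.22). Later B-cell genes had 4 of 15 tested members higher and 4 lower (5 higher and 4 lower adjusted over the list alone, median 0.38 log2, adjusted p = 0.787, median from -0.32 without recipient 1308 to 1.32 without recipient 1301, and -0.50 without recipients 1300 and 1308). Il2ra, which encodes CD25, was at 2625 ± 881 against 199.5 ± 43.6 and the kinase gene Syk at 4010 ± 867 against 9135 ± 1597. Enpep, Vat1l and Gldc had the largest falls, at 10.1 ± 15 (2.87 without recipient 1308), 2.48 ± 3.51 and 1.97 ± 1.32 in P80R B-ALL against 19069 ± 573, 3280 ± 297 and 2997 ± 286.

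All 28 G2/M genes were lower in P80R B-ALL (median -1.52 log2, adjusted p = 1.95e-15, adjusted p = 0.0947 with an estimated correlation). Nusap1 was at 7576 ± 1216 against 23664 ± 943. Of the S-phase genes, 2 of 26 tested members were higher and 17 lower (2 higher and 18 lower adjusted over the list alone, median -0.61 log2, adjusted p = 6.50e-05, adjusted p = 0.359 with an estimated correlation, median -0.38 without recipients 1300 and 1308). Clspn was at 839.9 ± 209 against 2517 ± 157. Interferon-response genes rose. Of this list, 25 of 27 tested members were higher and 2 not past the threshold (median 3.61 log2, adjusted p = 2.24e-10, adjusted p = 0.158 with an estimated correlation). Irf9 was at 3044 ± 589 against 306 ± 32.3 and Oasl1 at 1064 ± 552 against 1.89 ± 3.78. Cytosolic ribosomal protein genes rose. Of this list, 30 of 48 tested members were higher and 2 lower (31 higher and 2 lower adjusted over the list alone, median 0.45 log2, adjusted p = 1.78e-05, adjusted p = 0.559 with an estimated correlation), with Rps27 (log2 difference 1.25) leading. The mean log2 level of this list was 14.21 in recipient 1308, within the 13.90 to 14.23 of Pax5 WT, and 14.34 to 14.80 in the other recipients. Hypoxia-response genes were more often lower than higher: 4 of 33 tested members were higher and 17 lower (median -0.77 log2, adjusted p = 0.0168, adjusted p = 0.0947 with an estimated correlation, median -0.45 without recipients 1300 and 1308), with Bnip3 falling (log2 difference -1.78) and Slc2a3 rising (log2 difference 2.08). HIF pathway regulators had 2 of 10 tested members higher and 8 not past the threshold (median 0.07 log2, -0.04 with members at 0 in a group set to their bound, adjusted p = 0.893, median from -0.19 without recipient 1300 to 0.36 without recipient 1301, and -0.04 without recipients 1300 and 1308), the higher members being Epas1 and Vhl, and Hif1a was at 3778 ± 346 against 4230 ± 209.8 (adjusted p = 0.186).

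Markers of other cell types rose strongly in P80R B-ALL and differed widely between recipients. Hbb-bs, a beta-globin gene, was at 242008, 24039, 18622 and 562909 in recipients 1300, 1301, 1302 and 1308, with 1 read in all Pax5 WT libraries together, a ratio of 985400 (95% counting interval 160372 to 35292800). Without recipient 1308 this ratio was 441277, and without library 4 of Pax5 WT, which held the read, the fold was at least 72217. The alpha-globin genes Hba-a1 and Hba-a2 were at least 17172-fold and 16227-fold higher than the Pax5 WT floor (5887-fold and 4983-fold without recipient 1308), but reads of such near-identical copies cannot be assigned to either with certainty. Erythroid markers took 1.35% of reads in recipient 1300, 0.149% in 1301, 0.109% in 1302 and 2.91% in 1308. They had 10 of 12 tested members higher and 2 not past the threshold (11 higher and 0 lower adjusted over the list alone, median 8.27 log2, 7.79 with members at 0 in a group set to their bound, adjusted p = 4.66e-06, adjusted p = 0.274 with an estimated correlation). Granulocyte and monocyte markers took 0.519%, 0.0393%, 0.0206% and 0.544% of reads in the same order. They had 14 of 16 tested members higher and 2 not past the threshold (15 higher and 0 lower adjusted over the list alone, median 5.67 log2, 4.99 with members at 0 in a group set to their bound, adjusted p = 4.66e-06, adjusted p = 0.274 with an estimated correlation, median 3.76 without recipients 1300 and 1308). S100a8, a neutrophil gene, was at 67554 in recipient 1300 and 86.8 in recipient 1302, and at 0 in Pax5 WT. Macrophage markers had 11 of 11 tested members higher (median 8.70 log2, 7.85 with members at 0 in a group set to their bound, adjusted p = 7.02e-09, adjusted p = 0.121 with an estimated correlation). C1qc, a complement gene of macrophages, was at least 735-fold higher, or at least 327-fold without recipient 1308. With recipients 1301 and 1302 alone, in which erythroid and granulocyte markers were lowest, the medians of the G2/M, interferon-response and ribosomal protein lists were -1.31, 4.36 and 0.56 log2.

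**Figure D2:**
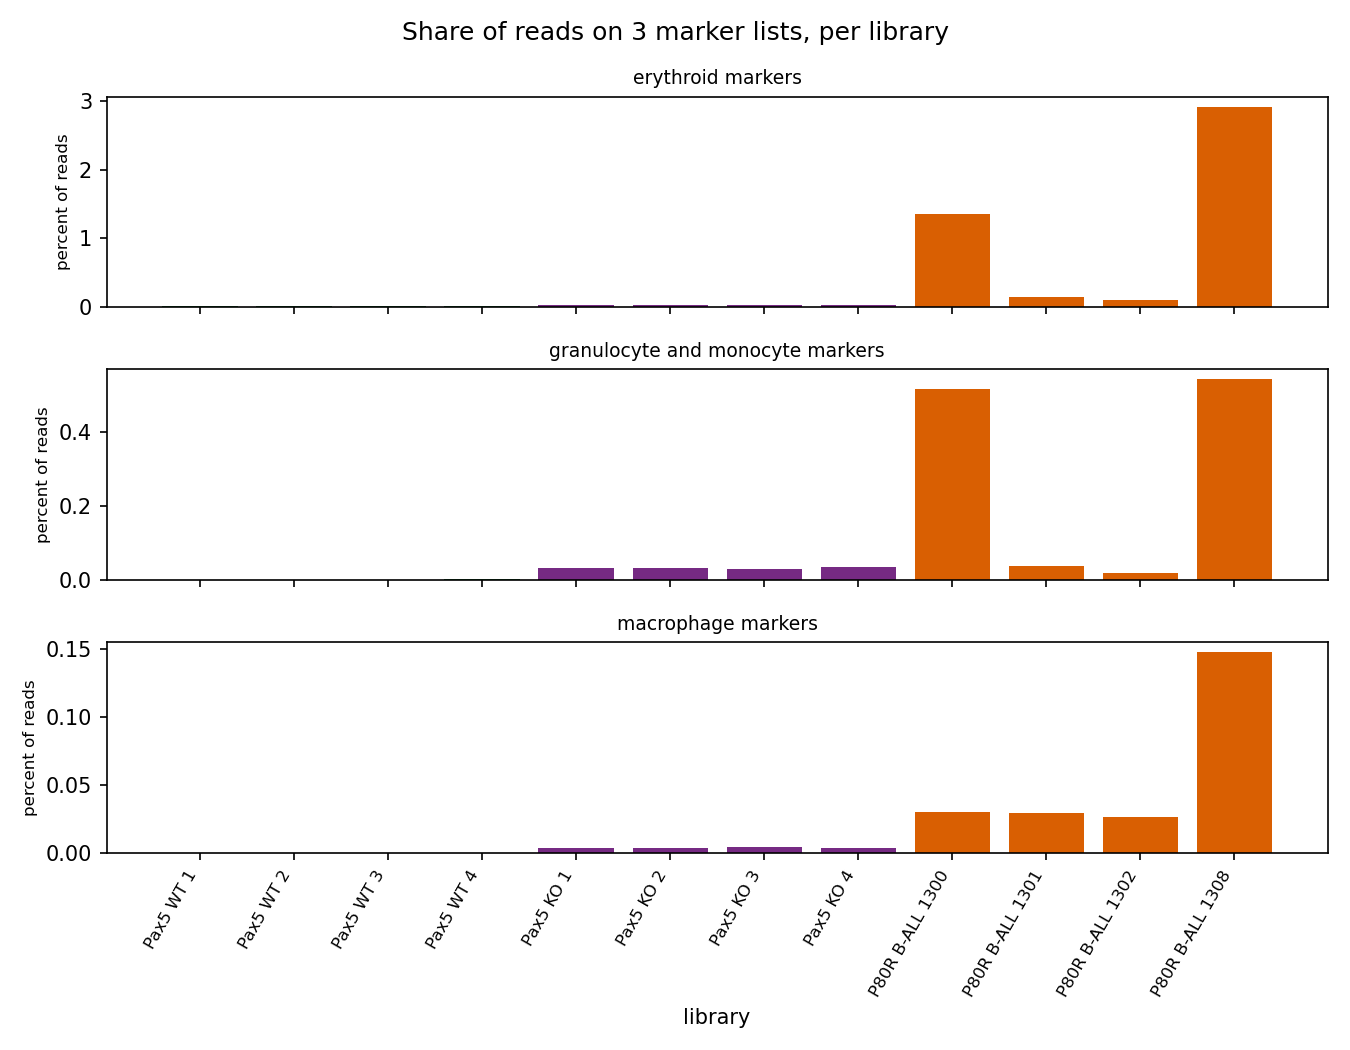
Percent of each library's reads on erythroid, granulocyte and monocyte, and macrophage markers, as 1 bar per library, with a separate scale in each panel starting at 0. Erythroid markers reached 2.91% of reads in recipient 1308 and 1.35% in recipient 1300.

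Lymphoid markers of other lineages also rose against Pax5 WT. T-lineage markers had 11 of 13 tested members higher and 2 not past the threshold (median 4.11 log2, 4.04 with members at 0 in a group set to their bound, adjusted p = 1.48e-05, adjusted p = 0.106 with an estimated correlation). The kinase gene Lck was at 8053 ± 3924 against 434 ± 56.4 and Cd4 at 1456 in recipient 1308 and between 124 and 169.6 in the other recipients. NK and innate lymphoid markers had 10 of 10 tested members higher (median 5.96 log2, 4.82 with members at 0 in a group set to their bound, adjusted p = 7.33e-06, adjusted p = 0.118 with an estimated correlation). Il18r1 was at least 255-fold higher. Plasmacytoid dendritic cell markers had 8 of 11 tested members higher and 3 not past the threshold (median 4.14 log2, adjusted p = 0.00113, adjusted p = 0.387 with an estimated correlation). Irf7 was at 2897 ± 2662 (1632 without recipient 1308) against 32.1 ± 15.7. Trf, the gene of the iron carrier transferrin, was at 16698 ± 6059 against 5.18 ± 2.23, and the 3 hepatocyte markers tested had 2 of 3 tested members higher and 1 not past the threshold (median 3.42 log2, adjusted p = 0.0946, median 2.19 without recipients 1300 and 1308). The 2 lists added after the data were seen also had higher members, with endothelial markers at 5 of 7 tested members higher and 2 not past the threshold (median 4.14 log2, adjusted p = 0.000466, adjusted p = 0.0507 with an estimated correlation). Stromal markers were at 9 of 9 tested members higher (median 6.72 log2, adjusted p = 7.56e-07, adjusted p = 0.0507 with an estimated correlation).

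The remaining lists did not pass the list test against Pax5 WT. Stem and multipotent progenitor genes had 3 of 13 tested members higher and 2 lower (median -0.29 log2, adjusted p = 0.907, median from -0.49 without recipient 1302 to -0.12 without library 2 of Pax5 WT, and -0.46 without recipients 1300 and 1308). The list had a mean log2 difference of 0.23 and a test direction of higher, opposite in sign to the median. Fetal-program genes had 2 of 10 tested members higher and 4 lower (median -0.88 log2, -0.43 with members at 0 in a group set to their bound, adjusted p = 0.26). Lin28b was at 3.46 ± 6.92 against 261 ± 61.9. Oxidative phosphorylation genes had 9 of 31 tested members higher and 3 lower (9 higher and 2 lower adjusted over the list alone, median 0.26 log2, adjusted p = 0.142, median from 0.08 without recipient 1301 to 0.33 without library 4 of Pax5 WT, adjusted p = 0.0325 without library 4 of Pax5 WT and 0.0319 without recipient 1302, and 0.0319 to 0.88 over all alternatives). Genes of the IL-7 receptor, JAK and STAT5 pathway had 5 of 22 tested members higher and 5 lower (median 0.03 log2, adjusted p = 0.893, median from -0.08 without recipient 1302 to 0.22 without recipient 1300, and 0.17 without recipients 1300 and 1308). RAS and MAPK feedback genes had 2 of 19 tested members higher and 2 lower (1 higher and 2 lower adjusted over the list alone, median -0.38 log2, adjusted p = 0.658, median from -0.43 without recipient 1308 to 0.33 without recipient 1301, and -0.78 without recipients 1300 and 1308). Their mean was 0.22, opposite in sign to the median. The p53 target genes had 3 of 17 tested members higher and 3 lower (median -0.05 log2, adjusted p = 0.893, median from -0.11 without recipient 1301 to -0.004 without recipient 1300, and -0.02 without recipients 1300 and 1308). Their mean was 0.03, and the sign of the median changed with the scaling. Immediate-early and heat-shock genes had 2 of 19 tested members higher and 7 lower (2 higher and 6 lower adjusted over the list alone, median -0.25 log2, adjusted p = 0.215, median from -0.28 without recipient 1308 to -0.08 without recipient 1301, adjusted p = 0.04999 without recipients 1300 and 1308 and 0.0436 without recipient 1308, and from 0.0334 with fry to 0.559 over all alternatives). Over the 12200 genes, limma called 6221, of which 3222 were higher and 2999 lower in P80R B-ALL (2310 and 2753 among genes with a CPM of at least 5), with recipient age and environment differing from fetal liver as well as genotype and stage. In simulated data with the spread of each group and 200 genes changed, 35.2% of the calls of this fit were false, or 0.63% of the unchanged genes, against 1.61% with the 8 libraries of the pair alone, which called 4873 genes here.

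**Figure D3:**
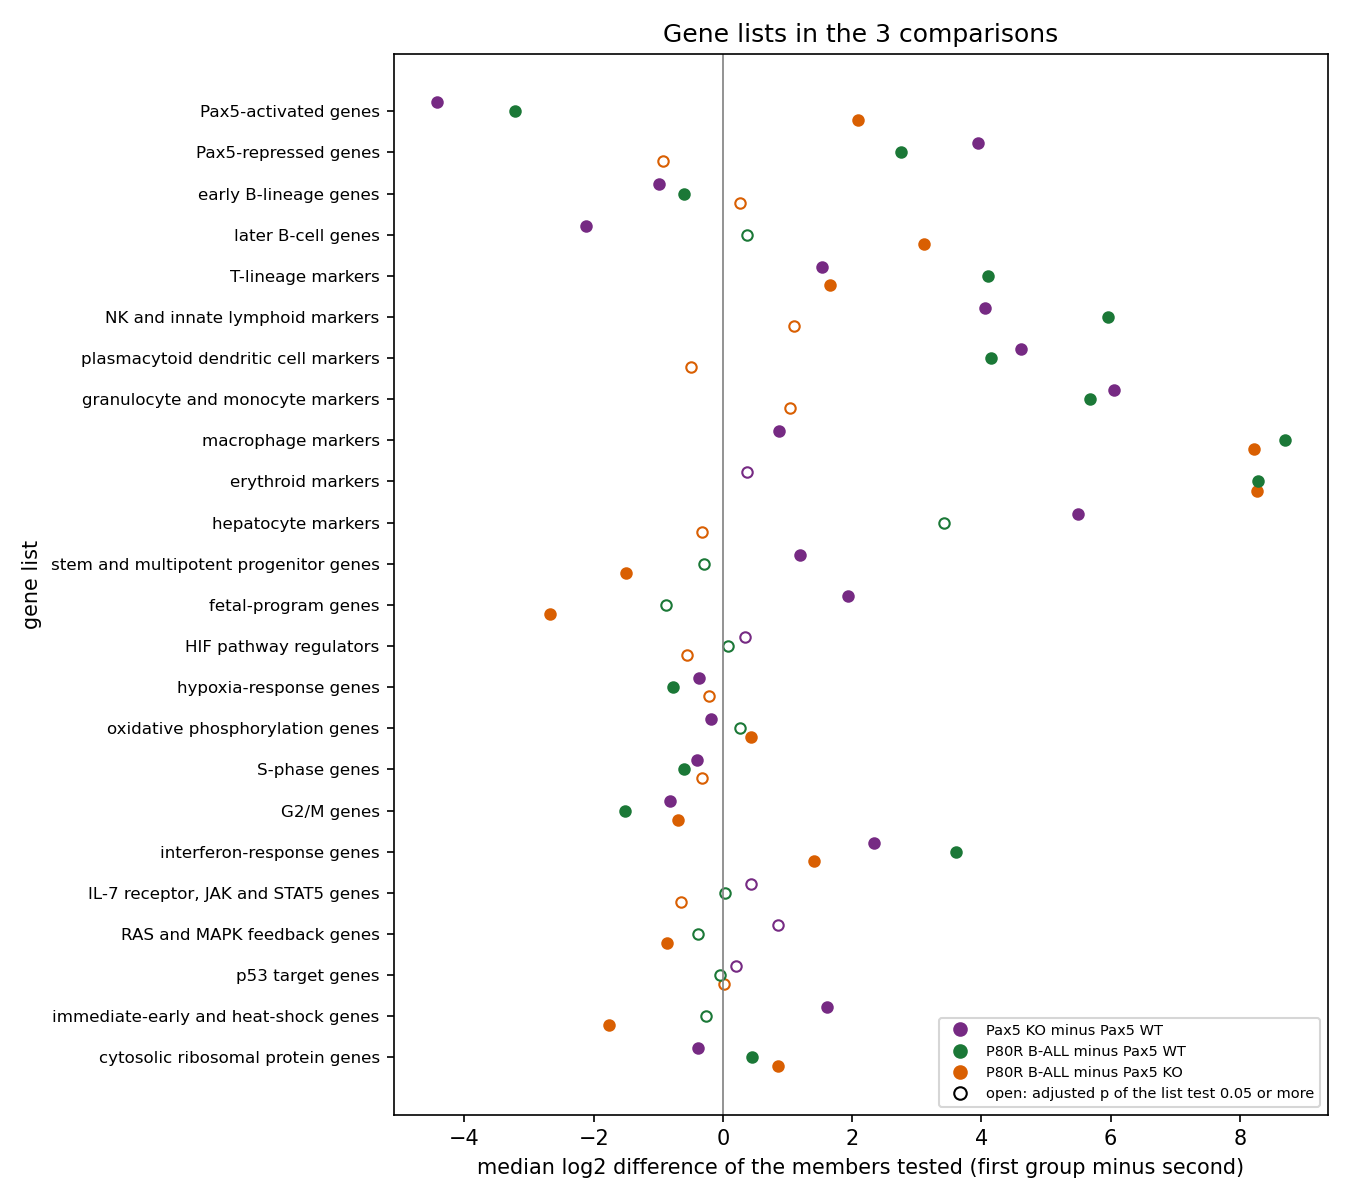
Median log2 difference of the tested members of each gene list (horizontal axis) in the 3 comparisons, with filled points where the list test passed an adjusted p of 0.05 at the preset correlation. Erythroid and macrophage markers had the largest medians in the P80R B-ALL comparisons, at 8.27 and 8.70 against Pax5 WT.

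The comparison of P80R B-ALL with Pax5 KO asks how the leukaemia differed from progenitors that lack Pax5. Epas1 was higher in every recipient. At the preset correlation the Pax5-activated list was higher and the stem, fetal-program and immediate-early lists lower, but none of these 4 lists passed at the estimated correlation. Without recipients 1300 and 1308, an omission chosen after the data were seen, these 4 lists passed at the estimated correlation in camera (adjusted p = 0.0332, 0.035, 0.035 and 0.0141 in this order). Epas1 was at 162 ± 35.3 against 5.14 ± 3.12 (log2 difference 4.87 ± 0.74 SE, adjusted p = 0.000277), with every B-ALL library above every Pax5 KO library. Pax5 was higher on average (log2 difference 1.58 ± 0.39 SE, adjusted p = 0.00547), but recipient 1308, at 255, lay within the Pax5 KO range. Flt3 was lower (log2 difference -1.60 ± 0.47 SE, adjusted p = 0.0135), and Ebf1 did not pass (log2 difference 0.01 ± 0.35 SE, adjusted p = 0.976), although it did without recipient 1308 (adjusted p = 0.0295) and without recipients 1300 and 1308 (adjusted p = 0.00316, with 0.00316 to 0.997 over all alternatives). Hif1a was slightly lower (log2 difference -0.37 ± 0.10 SE, adjusted p = 0.00912), a call that was lost when each group had its own weight (adjusted p = 0.149, with 0.00236 to 0.149 over all alternatives).

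Among Pax5-activated genes, 12 of 19 tested members were higher and 7 not past the threshold (12 higher and 1 lower adjusted over the list alone, median 2.09 log2, adjusted p = 0.000336, adjusted p = 0.144 with an estimated correlation). Slamf6 was at 3916 ± 2951 against 10.1 ± 3.78 and Blnk at 4824 ± 3576 (3192 without recipient 1308) against 116 ± 17.2. Pax5-repressed genes had 2 of 15 tested members higher and 4 lower (median -0.93 log2, adjusted p = 0.663, median from -0.97 without library 1 of Pax5 KO to -0.20 without recipient 1302). Notch1 was at 1304 ± 604 against 10185 ± 638 and the chemokine gene Ccl3 at 266 ± 227 (168 without recipient 1308) against 2174 ± 264. Early B-lineage genes had 6 of 19 tested members higher and 4 lower (median 0.26 log2, adjusted p = 0.0674, median from -0.07 without recipient 1301 to 0.66 without recipient 1308, and 0.65 without recipients 1300 and 1308, adjusted p = 0.00338 without recipients 1300 and 1308, 0.0286 without recipient 1300 and 0.034 without recipient 1308, and from 6.72e-05 with fry to 0.325 over all alternatives). Vpreb3 was at 8383 ± 3316 against 24.7 ± 12.7 and Cd79b at 23081 ± 5749 against 3423 ± 68.2. Later B-cell genes rose. Of this list, 10 of 15 tested members were higher and 2 lower (median 3.11 log2, adjusted p = 0.00224, adjusted p = 0.309 with an estimated correlation, median 1.67 without recipients 1300 and 1308). Il2ra was at 2625 ± 881 against 291 ± 31.6 and the MHC class II gene H2-Ab1 at 69641 in recipient 1308 and between 1249 and 1950 in the others.

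Of the stem and multipotent progenitor genes, 6 of 13 tested members were lower and 7 not past the threshold (median -1.50 log2, adjusted p = 0.0097, adjusted p = 0.144 with an estimated correlation). Cd34 was at 12.6 ± 11.7 against 2706 ± 207 and Hoxa7 at 3.69 ± 5.22 against 662 ± 56.4. Fetal-program genes fell. Of this list, 7 of 10 tested members were lower and 3 not past the threshold (median -2.67 log2, -2.01 with members at 0 in a group set to their bound, adjusted p = 0.00224, adjusted p = 0.144 with an estimated correlation). Hmga2 was at 2.32 ± 3.77 against 3695 ± 281 and Lin28b at 3.46 ± 6.92 against 668 ± 74.1. Immediate-early and heat-shock genes fell. Of this list, 2 of 19 tested members were higher and 12 lower (2 higher and 13 lower adjusted over the list alone, median -1.76 log2, adjusted p = 0.000165, adjusted p = 0.181 with an estimated correlation). Egr1 was at 169 ± 130.2 (105 without recipient 1308) against 26411 ± 956. RAS and MAPK feedback genes had 7 of 19 tested members lower and 12 not past the threshold (0 higher and 6 lower adjusted over the list alone, median -0.87 log2, adjusted p = 0.032, adjusted p = 0.549 with an estimated correlation, median -1.79 without recipients 1300 and 1308, median -0.42 without recipient 1301, adjusted p = 0.384 without recipient 1301, and 0.000755 to 0.549 over all alternatives). Dusp5 was at 1332 ± 909 against 11949 ± 204. Of the G2/M genes, 21 of 28 tested members were lower and 7 not past the threshold (0 higher and 24 lower adjusted over the list alone, median -0.69 log2, adjusted p = 1.38e-05, adjusted p = 0.309 with an estimated correlation, median -0.45 without recipients 1300 and 1308). Kif23 was at 2864 ± 613 against 7808 ± 492. S-phase genes went both ways, with 7 of 26 tested members higher and 12 lower (7 higher and 13 lower adjusted over the list alone, median -0.33 log2, adjusted p = 0.663, median from -0.43 without recipient 1301 to -0.22 without recipient 1308, and -0.01 without recipients 1300 and 1308) and Tyms, thymidylate synthase, higher (log2 difference 1.32).

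Cytosolic ribosomal protein genes rose. Of this list, 42 of 48 tested members were higher and 6 not past the threshold (45 higher and 0 lower adjusted over the list alone, median 0.85 log2, adjusted p = 8.26e-17, adjusted p = 0.309 with an estimated correlation). Rps19 was at 57369 ± 10559 against 24108 ± 794. Oxidative phosphorylation genes rose. Of this list, 18 of 31 tested members were higher and 2 lower (median 0.44 log2, adjusted p = 0.000732, adjusted p = 0.549 with an estimated correlation, median 0.28 without recipient 1301). Cycs, cytochrome c, was at 10954 ± 1415 against 4422 ± 336. Of the interferon-response genes, 18 of 27 tested members were higher and 9 not past the threshold (median 1.41 log2, adjusted p = 7.50e-06, adjusted p = 0.309 with an estimated correlation). The mean log2 level of this list was 8.62 in recipient 1300, near the 8.21 to 8.39 of Pax5 KO, and 10.37 to 10.87 in the other recipients. Gbp2 was at 2134 ± 1070 against 173 ± 17.9. HIF pathway regulators other than Epas1 were mostly lower, with 1 of 10 tested members higher and 7 lower (2 higher and 7 lower adjusted over the list alone, median -0.56 log2, adjusted p = 0.188). Hypoxia-response genes had 6 of 33 tested members higher and 10 lower (median -0.21 log2, adjusted p = 0.567), Ero1l (log2 difference -1.26) and Aldoa (log2 difference -1.13) being lower. Genes of the IL-7 receptor, JAK and STAT5 pathway had 2 of 22 tested members higher and 9 lower (median -0.65 log2, adjusted p = 0.188, median from -0.75 without recipient 1302 to -0.42 without recipient 1301). Osm was at 207 ± 71.5 against 27.1 ± 4.84. The p53 target genes had 3 of 17 tested members higher and 5 lower (median 0.02 log2, adjusted p = 0.827, median from -0.10 without recipient 1302 to 0.08 without library 1 of Pax5 KO, and -0.20 without recipients 1300 and 1308). Their mean was -0.24, opposite in sign to the median. In that list Cdkn2a, which encodes p16 and p19Arf, was higher, with 2 reads in all Pax5 KO libraries together and a ratio of 109.7 (95% counting interval 29.2 to 872), or at least 17.4-fold without library 1 of Pax5 KO, which held both reads. Cdkn2a was at 27.1 to 62.0 in the P80R B-ALL libraries and at 39.0 to 71.4 in those of Pax5 WT. Cdkn1a was lower than in Pax5 KO (log2 difference -2.14).

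Erythroid markers had 8 of 12 tested members higher and 4 not past the threshold (median 8.26 log2, 7.38 with members at 0 in a group set to their bound, adjusted p = 4.50e-06, adjusted p = 0.309 with an estimated correlation). Macrophage markers had 9 of 11 tested members higher and 2 not past the threshold (10 higher and 0 lower adjusted over the list alone, median 8.22 log2, 6.95 with members at 0 in a group set to their bound, adjusted p = 3.70e-07, adjusted p = 0.252 with an estimated correlation). Vcam1 was at 3222 ± 2627 (1919 without recipient 1308) against 8.82 ± 4.66. Granulocyte and monocyte markers, already present in Pax5 KO, had 5 of 16 tested members higher and 3 lower (median 1.03 log2, adjusted p = 0.35, median from -0.01 without recipient 1308 to 2.00 without recipient 1302, and -0.93 without recipients 1300 and 1308). Lyz2 was at 14226 ± 11619 against 1807 ± 90.9. T-lineage markers had 8 of 13 tested members higher and 5 not past the threshold (median 1.65 log2, adjusted p = 0.0149, adjusted p = 0.309 with an estimated correlation, adjusted p = 0.0784 without recipients 1300 and 1308, and from 0.00141 with fry to 0.309 over all alternatives). Cd3d was at 272 ± 316 (114 without recipient 1308) against 3.3 ± 1.83. NK and innate lymphoid markers had 4 of 10 tested members higher and 6 not past the threshold (median 1.11 log2, adjusted p = 0.134, median from 0.50 without recipient 1308 to 1.46 without recipient 1300, and 0.54 without recipients 1300 and 1308, adjusted p = 0.0472 without recipient 1300, and 0.0472 to 0.682 over all alternatives). Plasmacytoid dendritic cell markers had 2 of 11 tested members higher and 9 not past the threshold (0 higher and 0 lower adjusted over the list alone, median -0.49 log2, adjusted p = 0.663, median from -1.88 without recipient 1308 to 0.80 without recipient 1302, and -2.38 without recipients 1300 and 1308). The test direction was higher, opposite in sign to the median. Both higher members, Cadm1 and Tcf4, lost their call with the 8 libraries of the pair alone. The 3 hepatocyte markers had 1 of 3 tested members higher and 2 not past the threshold (1 higher and 1 lower adjusted over the list alone, median -0.32 log2, adjusted p = 0.495, median from -0.61 without recipient 1301 to 0.09 without recipient 1302, and -0.51 without recipients 1300 and 1308), the higher member being Trf. With recipients 1301 and 1302 alone, the medians of the G2/M, interferon-response and ribosomal protein lists were -0.45, 1.58 and 0.99 log2. Endothelial markers had 3 of 7 tested members higher and 1 lower (median 0.99 log2, adjusted p = 0.133, median from 0.37 without recipient 1308 to 2.30 without recipient 1302, and 0.03 without recipients 1300 and 1308). Stromal markers had 7 of 9 tested members higher and 1 lower (median 6.37 log2, adjusted p = 0.000389, adjusted p = 0.174 with an estimated correlation). Over the 12200 genes, limma called 5888, of which 2633 were higher and 3255 lower in P80R B-ALL, with age and environment confounded with genotype. More genes were higher than lower with RLE scaling (3006 and 2789), upper-quartile scaling (2949 and 2805), voom (2360 and 1771), DESeq2 (3777 and 2616) and edgeR (3161 and 2466). In simulated data with 200 genes changed, 39.0% of the calls of this fit were false, or 0.71% of the unchanged genes, against 3.39% with the 8 libraries of the pair alone, which called 4683 genes here.

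Genes that set the leukaemia apart from both fetal liver populations were then counted. Of the genes called in both comparisons, 1727 were higher and 1832 lower in P80R B-ALL than in both groups, 3559 in all, Epas1, Il2ra and Irf9 being among the higher ones. Voom with a weight per group gave 2353 genes. In simulated data with 200 genes changed, 39.0% and 35.2% of the calls of limma were false in the comparisons with Pax5 KO and Pax5 WT. The false calls were 0.71% and 0.63% of the unchanged genes. Far more genes were called in the real data, so these shares of false calls need not carry over to the shared genes. Lists drawn independently would share 695 and 800 genes in these directions, and unchanged groups that share the B-ALL libraries gave 36.4 genes on average over 20 simulations. With the B-ALL libraries divided between the comparisons, 2 against each group, 3243 to 3530 genes were shared over the 6 assignments. The log2 differences of the 2 comparisons correlated across genes with r = 0.55 (genes are not independent replicates), below the 0.884 of unchanged groups that share the B-ALL libraries, and with 0.321 to 0.478 when the B-ALL libraries were divided. The covariance was 1.72 against 0.294 from shared libraries alone. Another 335 genes were called in opposite directions, against 1507 for independent lists, and 599 to 1006 with the B-ALL libraries divided.

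The position of each leukaemia between the 2 fetal liver populations was measured over genes that differed between Pax5 KO and Pax5 WT, where 0 is the Pax5 WT mean and 1 the Pax5 KO mean. Recipients 1300, 1301, 1302 and 1308 lay at 0.725, 0.641, 0.620 and 0.855, with a mean of 0.710 ± 0.107. Between 4519 and 7516 genes entered each of the 36 divisions of the Pax5 KO and Pax5 WT libraries into a choosing and a measuring set. Members of the marker lists were not excluded from these genes.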

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

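The tests of marker ranks, of dilution and of other splits of the libraries were chosen only after the results were seen. In each group of 4 libraries, the gap between the highest or lowest library and its nearest neighbour was divided by the group's range, for the genes given by the naming rule and for each list mean. This ratio passed Dixon's critical value of 0.829 in 41 of 406 groups, where chance gives about 1 in 20, or 20.3. In 15 of these groups the gene was above 0 in 1 library alone, which always gives a ratio of 1, and in the other 391 groups the ratio passed in 26, where chance gives about 19.6.

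Recipient 1308 stood highest among the P80R B-ALL libraries in 10 of these groups. Its mean log2 level of macrophage markers was 11.99, the next library being at 9.44 (ratio 0.929). Plasmacytoid dendritic cell markers were at 13.48 against 8.20 (ratio 0.863), and NK and innate lymphoid markers at 10.20 against 8.04 (ratio 0.839). H2-Ab1 was at 16.09 against 10.93 (ratio 0.889), C1qc at 12.45 against 10.14 (ratio 0.836) and Cd4 at 10.51 against 7.41 (ratio 0.874). Ephb2, Ccn3, Lin28b and Arnt2 were above 0 in recipient 1308 alone of the P80R B-ALL libraries (ratio 1), at log2 levels of 6.05, 2.71, 3.89 and 3.75.

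The B-ALL libraries carried erythroid, granulocyte and macrophage transcripts in unequal amounts, although the cells had been sorted on GFP, which would remove cells without the construct. Within each list the members ranked the 4 libraries alike, with Kendall's W of 0.736 for erythroid, 0.729 for granulocyte and monocyte and 0.597 for macrophage markers (permutation p = 1e-04 each, the smallest that 10000 permutations can give). The permutations treated members as independent, and genes regulated together in the leukaemia cells would also rank the libraries alike. RNA of such other cells is thus a candidate source that this test cannot tell apart from expression by the leukaemia cells. The most abundant genes moved with these markers, Hbb-bs from 18622 in recipient 1302 to 562909 in recipient 1308 and S100a8 from 86.8 to 77275, but 5 of 12 erythroid, 5 of 11 macrophage and all 16 granulocyte members also reached a mean of 10 in Pax5 KO or Pax5 WT. With recipients 1301 and 1302 alone the median of the G2/M genes against Pax5 WT was -1.31 log2 (adjusted p = 1.05e-13, or 0.00343 with an estimated correlation), which argues against dilution by such RNA in recipients 1300 and 1308 as the whole cause of the lower level, while against Pax5 KO it went from -0.69 to -0.45 (adjusted p = 0.000755, or 0.0598 with an estimated correlation), so dilution stays open there. The mean log2 level of macrophage markers was 9.44 and 9.24 in recipients 1301 and 1302, near the 9.27 of recipient 1300. Leaving out recipients 1300 and 1308 therefore does not bear on dilution in recipients 1301 and 1302. Expression of the erythroid, granulocyte and macrophage markers by the leukaemia cells themselves, and differences between recipients in disease or organ, stay open as untested.

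Recipient 1300 was lowest among the P80R B-ALL libraries for Aldoa (log2 level 12.34, ratio 0.843), Xaf1 (9.77, ratio 0.860) and Irf9 (11.09, ratio 0.850). Recipient 1302 was lowest for Rps27 (14.62, ratio 0.885), and recipient 1301 for Gldc, at 0 (ratio 0.940). Library 4 of Pax5 WT was lowest for Notch1 (8.43, the next library being at 9.60, ratio 0.999), Slc2a3 (8.60, ratio 0.867) and Mrc1 (0, ratio 0.922), and highest for Ube2c (14.40, ratio 0.837), Car2 (12.41, ratio 0.851) and the mean of hypoxia-response genes (10.38, ratio 0.893). Library 3 of Pax5 WT was highest for Zmat3 (8.62, ratio 0.866), and library 1 of Pax5 WT lowest for Trf (1.53, ratio 0.872). Library 1 of Pax5 KO was highest for Ebf1 (12.70, ratio 0.855), S100a8 (7.61, ratio 0.835) and Irf9 (10.52, ratio 0.831). Library 3 of Pax5 KO was lowest for Irf7 (9.51, ratio 0.835) and Zmat3 (7.15, ratio 0.990), and library 4 of Pax5 KO for Gbp2 (7.20, ratio 0.928) and Bnip3 (9.99, ratio 0.928). In a further 11 groups a gene was above 0 in 1 library alone (ratio 1), which were Hbb-bs and Hoxa10 in library 4, Alas2, Fcgr3 and Oasl1 in library 1 and Afp in library 3 of Pax5 WT, and Cdkn2a and Enpep in library 1, Egfl6 and Ms4a1 in library 2 and Hba-a1 in library 3 of Pax5 KO.

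Other splits of the 8 libraries of each pair into 4 and 4 were refitted with limma. There were 35 in each comparison with the real split included. Only the real split gave as many genes, a share of 1 in 35, the smallest these splits can give. Every other split mixed the groups of the pair, so their difference entered the spread and held the count down. The counts therefore cannot tell how many of the calls are due to chance, and no conclusion is drawn from them. For P80R B-ALL and Pax5 KO the real split called 5888 genes and the highest other 0, or at most 3083 at an unadjusted p under 0.05. For P80R B-ALL and Pax5 WT these were 6221 and 802, the latter with recipient 1302 in place of library 4 of Pax5 WT. For Pax5 KO and Pax5 WT they were 4193 and 0, or at most 371 at an unadjusted p under 0.05.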

How the results depend on the processing

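The edgeR test on recovered reads, TMM scaling, the other pseudocounts, thinning, the omission of recipients 1300 and 1308 together and all omissions for endothelial and stromal markers were chosen only after the data were seen, and the other alternatives before. No called result changed direction under any of them, and the counts for both P80R B-ALL comparisons stayed within 1.5 times in all of them. The count for Pax5 KO and Pax5 WT, 4193 with the shared spread, was 7901 with the 8 libraries of the pair alone, 8011 with voom and a weight per group, and 6301 without recipients 1300 and 1308, each of which took some or all of the variable B-ALL libraries out of the spread or weighed them down. With a replicate block, which was fitted to the 8 Pax5 KO and Pax5 WT libraries alone, it was 7987, close to the 7901 of that pair without a block. Libraries with the same number deviated together with correlations of 0.00493, 0.022, 0.032 and 0.062, all under 0.1, and 1 of 4 correlated best with its own number, so the numbers were not taken as pairs. The genes that differed in P80R B-ALL from both groups in the same direction fell to 2353 with voom and a weight per group. In simulated data 9.59% of the voom calls against Pax5 KO and 4.51% against Pax5 WT were false. For limma fitted to all libraries these shares were 39.0% and 35.2%. Fewer false calls may thus be part of the fall, but how much of it they explain was not tested. With the estimated correlation, 0 of 24 lists passed for P80R B-ALL and Pax5 KO, 0 for P80R B-ALL and Pax5 WT and 3 for Pax5 KO and Pax5 WT, against 13, 14 and 19 at the preset correlation of camera. Fry, which tests a list against no change rather than against the other genes, passed 18, 18 and 20. Without recipients 1300 and 1308, some lists passed at the estimated correlation in each comparison. For Pax5 KO and Pax5 WT the later B-cell, macrophage, hepatocyte, oxidative phosphorylation and ribosomal protein lists still did not. The other lists called there at the preset correlation did, G2/M genes with adjusted p = 0.00357 and interferon-response genes with 0.00779 in camera. For P80R B-ALL against Pax5 WT the early B-lineage, S-phase and ribosomal protein lists still did not. Against Pax5 KO the later B-cell, T-lineage, oxidative phosphorylation, G2/M, RAS and MAPK feedback and ribosomal protein lists still did not. At the preset correlation, 3 list calls ended without these recipients, of T-lineage markers for P80R B-ALL and Pax5 KO (median 1.65 before and 1.499 after), early B-lineage genes for P80R B-ALL and Pax5 WT and hepatocyte markers for Pax5 KO and Pax5 WT, and 4 lists passed that had not. Leaving out each library in turn gave 4856 to 6460 genes for P80R B-ALL and Pax5 KO, 5303 to 6742 for P80R B-ALL and Pax5 WT, 3312 to 5217 for Pax5 KO and Pax5 WT, 2992 to 4208 shared genes and positions of 0.662 to 0.740, and 12 to 15, 14 to 15 and 18 to 21 lists. Other scalings moved the median of all genes by at most 0.088 and the share of higher calls by at most 7.15 percentage points, while for P80R B-ALL and Pax5 KO that share was 44.7% in limma, 51.9% with RLE and 51.3% with upper-quartile scaling, 59.1% in DESeq2 and 56.2% in edgeR on recovered reads. Of 258 results for single genes, 237 kept their side of the threshold in every alternative run for them (24 to 27 settings each), 11 lost it somewhere (such as Tcf4 and Cadm1 for P80R B-ALL and Pax5 KO) and 10 passed it somewhere. Thinning all libraries to the smallest gave 5882, 6236 and 4168 genes, so the difference in depth changed the counts little. The heavy-chain V segments alone were not run, since V segments were not analysed here.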

Other observations

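The tests on Epas1 and the genes picked by their spread between recipients were chosen only after the values were seen, as was the comparison of ribosomal protein genes with other short genes, while the test of matched genes was set before its result was seen. Some genes were raised to a similar level in all 4 leukaemias. In 561 genes P80R B-ALL was higher than both fetal liver groups with a range of at most 1 on the log2 scale between recipients. Esr1, the estrogen receptor gene, was at 1010 ± 301 against 49.8 ± 12.3 in Pax5 KO and 13.1 ± 4.19 in Pax5 WT. Nlrc4, an inflammasome gene, was at 802 ± 69.2 against 37.7 ± 8.3 and 73.3 ± 16, and Rapgef3, a cyclic AMP sensor, at 1609 ± 391 against 129 ± 26.7 and 16.9 ± 7.41. The interferon-inducible GTPase gene Ifi47 was at 11839 ± 3296 against 1691 ± 147 and 992 ± 42.3.

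Other genes differed between the B-ALL libraries by several orders of magnitude. Dntt, the terminal transferase of lymphoid progenitors, was at 115932, 45518, 127 and 12925 in recipients 1300, 1301, 1302 and 1308. Ccnd1, the gene of cyclin D1, was at 4167, 25.8, 4410 and 17650 in the same order, and Cdh17, a cadherin gene, at 9627, 0, 14583 and 20014. Recipient 1308 had the highest Siglech, at 26551, and the highest level of the chemokine receptor gene Ccr9, at 25992, the next being 325 and 1677 in recipient 1302. Siglech is a plasmacytoid dendritic cell gene, and the mean log2 level of such markers was 13.48 in recipient 1308 and at most 8.20 in the others. Whether these differences lie in the leukaemia cells or in RNA of other cells was not tested.

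Epas1 was higher in all 4 leukaemias than in any fetal liver library, and in recipient 1308 it was 1.16 times its level in recipient 1302 (95% counting interval 0.917 to 1.47) and 1.56 times that in recipient 1301 (1.20 to 2.01). T-lineage, macrophage and erythroid markers (3, 7 and 9 members with a mean under 10 in both fetal liver groups and of at least 20 in the other 3 recipients) had median ratios of at least 6.49 to recipient 1302 and 4.88 to recipient 1301, with lower quartiles of 4.71 and 3.31 or more, which argues against RNA of these cells as the source, although against recipient 1300 the erythroid ratio was 1.04 and that of Epas1 1.53. Endothelial and stromal markers (8 and 3 members) also had high ratios to recipient 1302 (10.2 and 6.93), but their ratios to recipient 1301 were 1.38 and 2.43, near that of Epas1, so the evidence against them rests on recipient 1302 alone and RNA of such cells stays open. Scaling did not account for the difference, the lowest log2 difference over 3 other scalings and both comparisons being 4.86. Expression by the leukaemia cells, other cell types, the mutation, the stage and the age and environment of the recipients stay open as untested.

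Cytosolic ribosomal protein genes are short and abundant, so gene length bias was tested as the source of their rise in P80R B-ALL. Genes matched on exon length and level, outside the list, had a median log2 difference of 0.365 against Pax5 KO and 0.186 against Pax5 WT, where the list had 0.85 and 0.45, and 0 of 10000 draws reached the list's median in either comparison. The match was incomplete, the drawn genes having a median length of 1968.5 (2409 counting each gene once) against 1923.5 and a median level of 14.01 (13.72) against 14.27. The 36 other genes shorter than the list's median and at least as abundant as its lower quartile had medians of 0.74 and 0.36, close to the 0.83 and 0.42 of the 24 shorter members, so the bound set beforehand, on matched genes of all lengths, was too lenient to exclude length. Gene length, lower RNA quality and differences in stage stay open.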
